A study of Mus musculus with 36 samples.

How the data were processed

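Ribosome-bound RNA was measured by polysome fractionation followed by RNA sequencing in the cortex of female mouse embryos at embryonic day 14.5. Each sample was a pool of cortices of 2 embryos of 1 genotype. In this assay a cleared lysate is spun through a sucrose gradient, which parts RNAs by the number of ribosomes they carry. RNAs with a single ribosome collect in the monosome fraction and RNAs with several ribosomes in the polysome fraction. Per the labels' protocols, the gradients ran from 15 to 50% sucrose and were taken off in 12 fractions, the input was removed from the cleared lysate before loading, and libraries with reads of 50 bp were made with the KAPA HyperPrep kit. Which gradient fractions were joined as monosome and as polysome is not given in the sources used here, nor is the number of ribosomes they stand for.

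The labels put the 36 libraries in 12 groups of 3, from 2 crosses (named LoF and T532M), 2 genotypes and 3 fractions. In the LoF cross the conditional heterozygotes (cHet) carried Emx1-Cre and 1 lox-flanked Ddx3x allele, and their controls carried the lox-flanked allele without Cre. In the T532M cross the cHet carried Emx1-Cre and a Ddx3x-T532M lox allele, and their controls carried Emx1-Cre alone. Cre was thus in the cHet only in the LoF cross and in both genotypes in the T532M cross. The Emx1-Cre driver acts in the progenitors of the dorsal telencephalon and their progeny, so other cells of a pool keep their Ddx3x alleles. The labels do not say whether pools shared litters or days. The p-values measure the spread between libraries of the same group, pooled over the groups of a fit. The main fits treat all libraries as independent, although the 18 libraries of a cross come from 6 pools.

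The authors counted read pairs per gene, and these raw counts are deposited for 55487 genes. Per the file headers, featureCounts version 2.0.3 counted read pairs over whole gene spans, introns included, in the reverse-stranded setting (2), on the GENCODE release M25 annotation of the mouse genome GRCm38. Counting used strand, so overlapping antisense genes were told apart, but genes that overlap on 1 strand and near-identical copies were not. The submitters' processing notes also name FastQC 0.11.7, STAR 2.7.11a, Subread 2.0.3 and DESeq2 1.34.0, with no further settings. The authors' deposited tables, 1 for each cross, hold a log2 fold change, a p-value and an adjusted p-value for input, monosome and polysome, and a normalized signal per library, which is the count divided by 1 size factor for each library. Tested on the tables' own values above 200 normalized counts, the monosome and polysome columns are the fold in that fraction relative to the fold in input, so they answer another question than a comparison within a fraction.

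Tests were run on the deposited counts in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr filter, Benjamini-Hochberg adjustment, adjusted p under 0.05). Each cross was fitted on its 18 libraries with a term for each of the 6 groups. The filter left 18556 genes in the LoF cross, 18243 in the T532M cross and 19121 in the fit of all 36 libraries, which tested differences between the crosses. Comparisons were cHet against control in each fraction, the change of the genotype effect in polysomes over that in input or in monosomes, polysome against monosome in controls, and the LoF effect minus the T532M effect. Levels are in CPM, counts scaled by TMM library sizes, as mean ± SD of 3 pools.

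Gene lists (33, for cell types of the cortex and its borders, translation, mitochondria, stress and signalling) were fixed before the data were examined, as were the design, the rule for naming genes and most alternatives. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM (prior count 3), with Benjamini-Hochberg adjustment over the lists of each of the 10 genotype comparisons. Of the 330 list tests, 85 passed with the preset correlation and 0 with the correlation estimated from the data, where the lowest adjusted p was 0.0716. The list calls below therefore rest on the preset value. In the genotype comparisons, members given as higher or lower are counted by the sign of the fold change, whether or not they passed. In polysome against monosome of controls only members past the threshold are counted. The list called reported DDX3X-sensitive mRNAs holds transcripts known from earlier work on DDX3X and was fixed together with the others.

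Ddx3x was named first in every group. For each comparison the text names, among genes past the threshold with a mean of at least 2 CPM, an assigned gene name and, within 1 fraction, values of the groups that do not overlap, the 10 largest rises and the 10 largest falls. Up to 4 changed members of each list are named too. Where fewer than 5 genes passed, all of them and the 3 with the smallest p are named. In the comparison of fractions only list members are named. Genes outside this rule are said to be so, and some that the rule takes are not reported here.

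Library totals ran from 36999365 to 57935512 read pairs, with 33391 genes having at least 1 read pair. In all 36 pairs of replicates within a group the counts differed by far more than sampling noise (chi-square per degree of freedom 13.7 to 125), so the replicates of a group were not copies of each other. Libraries of different groups were not compared in this way. Genes of the Y chromosome (4 genes) had 0 to 75 read pairs in a library, in animals labelled female. Read pairs carry no molecular identifiers, so counting intervals cover counting error only.

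Numbers in the labels were checked for pairing. Fractions with the same number within a genotype come from the same lysate, as the input was taken from the lysate that was loaded. The deviations of all 36 such pairs of libraries from their group means correlated best with their own number (r from 0.0632 to 0.434). A fit with the lysate as a replicate block was therefore run for each comparison across fractions, and its value stands beside a result where it moved the count by over 1.5 times. Control and cHet pools of the same number were not paired by the labels (r from -0.315 to 0.185).

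Alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, a fit on 1 fraction or on all libraries, both blocks, leaving out each pool in turn, and for lists an estimated correlation and fry. Chosen after seeing the data were a correction of each library for transcript GC content and length, fits without the 3 LoF pools with most Ttr, and comparisons of the monosome with input and of the crosses in the monosome and in polysome over monosome. GC content and length came from the GENCODE release M21 transcripts, which covered 99.9% of the genes tested. The tests across genes were first tried on simulated counts drawn from the means and library sizes of these libraries, with 200 genes changed in each of 19 comparisons. They recovered from 25.8% (LoF effect minus T532M effect, in polysome over input and in polysome over monosome) to 93.2% of the genes changed by 2-fold and at least 80.0% of those changed by 4-fold. There were at most 12 false calls in a comparison, and 10 of 10 changed lists and 0 of the unchanged ones were called. Simulated genes and libraries varied independently, without shared lysates, GC trends or correlation between genes. The false calls therefore do not show how often the tests err where the real libraries hold these.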

Results

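The dataset measured which RNAs of the embryonic mouse cortex sedimented with single ribosomes (monosome) or with several (polysome). In cHet, 1 copy of Ddx3x was altered in the Emx1 lineage. Ddx3x is an X-linked gene for an RNA helicase that helps ribosomes scan structured 5' ends of mRNAs. There were 36 libraries, 3 for each of 12 groups, with 38059093 to 46271375 read pairs in input, 36999365 to 49049947 in the monosome and 44214830 to 57935512 in the polysome. Emx1, the dorsal cortical transcription factor whose promoter drives Cre, was at 61.4 to 90.1 CPM in input, 38 to 68.3 CPM in monosome and 26.1 to 42.4 CPM in polysome libraries. Xist, the RNA of the inactive X chromosome in females, was at 5.75 to 15.1 CPM in input. It was at 57.3 to 83.0 CPM in the monosome and 34.2 to 62.3 CPM in the polysome. Xist is on the fixed list of nuclear-retained RNAs, and mitochondrial RNA took 3.82 to 10.2% of monosome read pairs. Presence in a fraction therefore does not show that an RNA was on cytosolic ribosomes.

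Ddx3x itself (ENSMUSG00000000787.12, chromosome X, 13280970 to 13294052, plus strand of GRCm38) was measured first, as the gene the alleles target. In the LoF cross it was at 114.7 ± 36.2 CPM in control and 90.97 ± 27.4 CPM in cHet input (SD, n = 3). It was at 303 ± 35.5 and 210.3 ± 40 CPM in the monosome and at 2404 ± 272 and 1929 ± 295 CPM in the polysome. All 3 cHet monosome libraries (178 to 255 CPM) lay below the 3 controls (281 to 344 CPM), an order that chance gives in 10% of 3 against 3 comparisons. The log2 fold changes were -0.33 (SE 0.219, adjusted p = 0.703, edgeR), -0.53 (SE 0.218, unadjusted p = 0.0262, adjusted p = 1) and -0.32 (adjusted p = 1), so none passed. In the T532M cross Ddx3x was at 101.9 ± 48 CPM in control and 200.1 ± 34.5 CPM in cHet input. The cHet input libraries (166 to 235 CPM) lay above the controls (50.1 to 145 CPM). It was at 310.4 ± 31 and 301.5 ± 38.1 CPM in the monosome and at 2927 ± 608 and 5079 ± 886 CPM in the polysome, where the cHet libraries (4120 to 5860 CPM) again lay above the controls (2270 to 3470 CPM). These log2 fold changes were 0.97 (SE 0.273, adjusted p = 0.264), -0.04 (adjusted p = 0.974) and 0.80 (SE 0.271, adjusted p = 0.51). Without T532M control 2 the input change passed (adjusted p = 0.027), as it did without the low-count filter (adjusted p = 0.0118). Without the 3 LoF pools with most Ttr, a choice made after seeing the data that leaves 1 control, the LoF monosome change was -0.88 with an adjusted p of 0.00304. The counts cover the whole gene span, and the labels do not say which part is lox-flanked, so reads from outside that part cannot check the deletion.

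**Figure D1:**
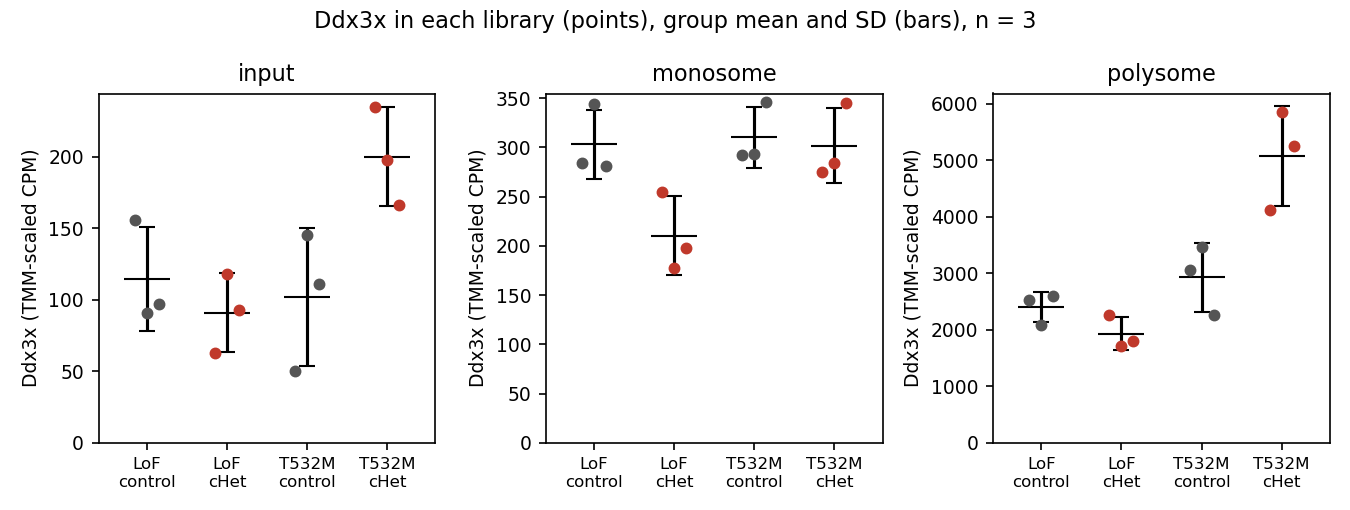
Ddx3x level (TMM-scaled CPM, vertical axes) in each library of input, monosome and polysome, by cross and genotype. Points are libraries, and bars show the mean and SD of 3 pools. In the LoF monosome the 3 cHet libraries (178 to 255 CPM) lie below the 3 control libraries (281 to 344 CPM), and in T532M input and polysome the 3 cHet libraries lie above the 3 controls.

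The question of what the 2 gradient fractions hold was answered by polysome against monosome in controls. Transcripts of ribosomal proteins, which have short coding regions, were lower in the polysome for 76 of 76 members in LoF controls (median log2 fold change -3.24). Rpl41 fell from 1500 ± 83.7 to 47.2 ± 0.846 CPM (log2 fold change -4.99, SE 0.174). Mitochondrially encoded mRNAs, translated by other ribosomes, were lower for 10 of 10 members (median -7.31), and hosts of small nucleolar RNAs for 11 of 11 (median -4.17), with Gas5 falling from 421.8 ± 15.6 to 25.3 ± 1.40 CPM. Atf4, whose upstream reading frames hold back its translation, fell from 429.4 ± 9.48 to 45.4 ± 2.98 CPM. Axon guidance and synapse genes were higher in the polysome for 21 of 22 members (median 2.65), such as the guidance receptor Robo1 (50.6 ± 6.07 to 629.3 ± 24 CPM). DEAD/DEAH-box helicases were higher for 26 of 28 (median 2.45), with Ddx3x at a log2 fold change of 2.99 (SE 0.234, adjusted p = 5.16e-10). Cell cycle genes were higher for 24 of 25 (median 1.70). The order held in T532M controls, with 76 of 77 ribosomal protein mRNAs lower (median -3.05), 10 of 10 mitochondrially encoded ones lower (median -5.63) and 25 of 25 cell cycle genes higher. In all, 15076 of 18556 genes differed in LoF controls (6746 higher, 8330 lower) and 14582 of 18243 in T532M controls (6570 higher, 8012 lower; edgeR). The values are shares of a library, and the median of all genes was -0.31 in both crosses, so they are relative.

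**Figure D2:**
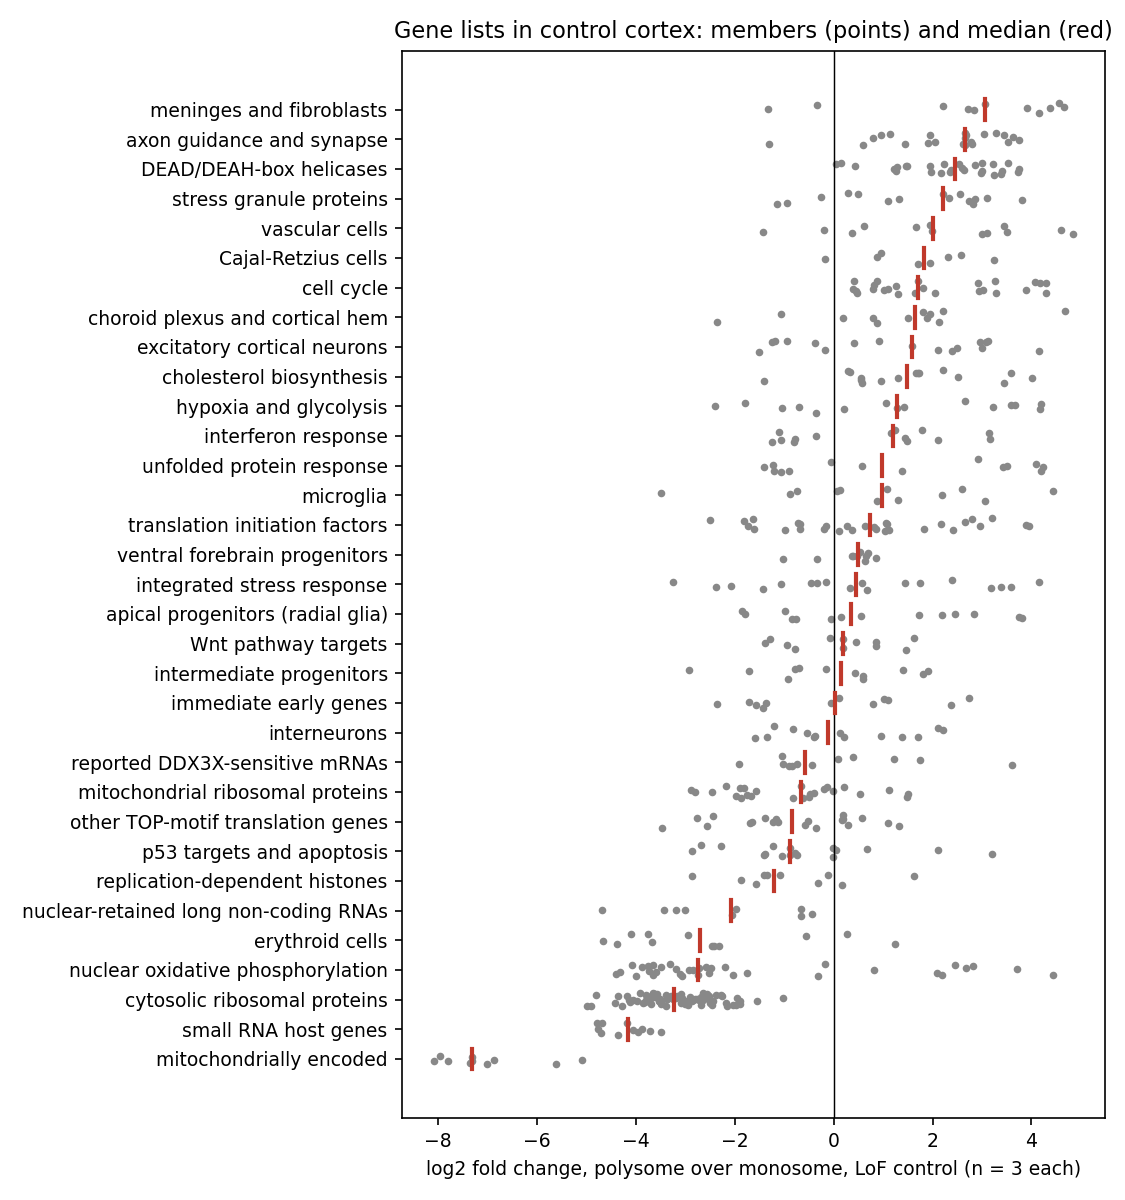
Log2 fold change of polysome over monosome in LoF controls (horizontal axis) for the members of the 33 gene lists (vertical axis). Grey points are genes and red marks are list medians. Ribosomal protein mRNAs have a median of -3.24 and axon guidance genes a median of 2.65.

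Input of LoF cHet against control asked which RNAs differed in the lysate itself. Here and in the genotype comparisons below, list members are counted by the sign of their fold change alone. The choroid plexus and cortical hem list, markers of the medial border of the cortex, was lower for 12 of 12 members (median -1.04, adjusted p = 0.00358, camera). That adjusted p = 0.851 with an estimated correlation. Its member Ttr, the thyroxine carrier made by the choroid plexus, was at 160, 1.48 and 183 CPM in control pools 1, 2 and 3 and at 39.3, 0.531 and 0.0441 CPM in cHet pools, so it follows single pools. Interneuron markers were lower for 13 of 14 members (median -0.33, adjusted p = 0.0117, and adjusted p = 0.851 with an estimated correlation), with the receptor Erbb4 at 3.32 ± 1.08 CPM in control and 1.5 ± 0.407 CPM in cHet. Axon guidance genes were lower for 17 of 22 (median -0.27, adjusted p = 0.0102, and adjusted p = 0.851 with an estimated correlation) and stress granule genes for 12 of 15 (median -0.30, adjusted p = 0.0113, and adjusted p = 0.851 with an estimated correlation). Ribosomal protein mRNAs were higher for 74 of 76 members (median 0.12, adjusted p = 3.86e-07, and adjusted p = 0.887 with an estimated correlation). With p-values adjusted over the list alone, 1 member each of the interneuron (Erbb4), choroid plexus (Rspo3) and axon guidance (Nlgn1) lists was lower. With the GC and length correction 3 of the 11 lists called stayed (interneurons, choroid plexus, ribosomal proteins), while stress granule and axon guidance genes were lost (adjusted p = 0.423 and 0.369). At the level of genes 0 of 18556 changed by edgeR, 1996 had an unadjusted p under 0.05, and DESeq2 called 81. The smallest p-values belonged to Gm15564 (4.00 ± 0.795 to 12.7 ± 0.578 CPM), the zinc finger gene Zfp458 (2.53 ± 0.107 to 1.44 ± 0.0979 CPM) and CT010467.2 (2.84 ± 1.38 to 13.95 ± 0.623 CPM), each with an adjusted p of 0.086. CT010467.1, which lies over a copy of the ribosomal RNA precursor and was chosen after its values were seen, took 4.74 ± 0.455% of the read pairs in cHet input and 1.23 ± 0.591% in control input. Without cHet 1 the count was 15, and without cHet 2 it was 4.

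In the LoF monosome the question was which RNAs differed in amount in cHet. Gm5380, a gene model 8233 bp downstream of Ddx3x on the same strand (chromosome X, 13302285 to 13304420), rose from 0.0206 to 2.59 ± 0.263 CPM (log2 fold change 6.87, SE 0.667, adjusted p = 7.02e-05). Its 3 control libraries held 3 read pairs and its 3 cHet libraries 380, a ratio of 134 (95% counting interval 45.4 to 651). In input Gm5380 had 2 and 51 read pairs (ratio 27, 95% counting interval 7.1 to 229, adjusted p = 0.109 by edgeR), and its change of monosome over input did not pass (adjusted p = 0.997), so a shift onto single ribosomes is not shown. Nyx, a gene for a leucine-rich proteoglycan 172058 bp downstream of Ddx3x (chromosome X, 13466110 to 13489313), rose from 0.286 ± 0.0626 to 1.66 ± 0.245 CPM (log2 fold change 2.52, SE 0.383, adjusted p = 0.0276). These were the 2 genes of 18556 that passed (edgeR). Unadjusted, 779 had a p under 0.05, and DESeq2 called 5. Nyx was lost without control 1, 2 or 3 (adjusted p = 0.0914, 0.111 and 0.527), without cHet 2 or 3 (0.25 and 0.706) and in a fit on the monosome alone (0.0924). The third smallest p belonged to the ribosome-associated gene Tma7 (166 ± 4.18 to 119.7 ± 6.71 CPM, adjusted p = 1). Without cHet 1 the count was 180, and it was 1 without any other library. Without the 3 pools with most Ttr it was 940.

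Erythroid transcripts were lower in the LoF cHet monosome for 12 of 12 members (median -0.61, adjusted p = 1.4e-08, and adjusted p = 0.195 with an estimated correlation), with the globin Hbb-bt at 71.1 ± 1.41 CPM in control and 46.7 ± 10.9 CPM in cHet. Mitochondrially encoded mRNAs were lower for 10 of 10 (median -0.52, adjusted p = 1.15e-05, and adjusted p = 0.306 with an estimated correlation). The cytochrome oxidase subunit mt-Co1 stood at 24170 ± 8030 CPM in control and 16800 ± 3150 CPM in cHet. Choroid plexus and hem markers were lower for 12 of 12 (median -0.84, adjusted p = 0.000237, and adjusted p = 0.429 with an estimated correlation), ventral forebrain progenitor markers for 10 of 10 (median -0.24, adjusted p = 0.00071, and adjusted p = 0.316 with an estimated correlation) and interneuron markers for 13 of 14 (median -0.28, adjusted p = 0.00125, and adjusted p = 0.481 with an estimated correlation). Microglial markers were lower for 10 of 12 (median -0.24, adjusted p = 0.00174, and adjusted p = 0.195 with an estimated correlation), with the complement gene C1qc at 2.01 ± 0.321 and 1.15 ± 0.403 CPM. Immediate early genes, induced by stimuli and by handling, were lower for 10 of 12 (median -0.23, adjusted p = 0.00125, and adjusted p = 0.0716 with an estimated correlation). Reported DDX3X-sensitive mRNAs were higher for 11 of 12 (median 0.13, adjusted p = 0.00374, and adjusted p = 0.21 with an estimated correlation), with the corepressor gene Rcor2 at 109.5 ± 1.3 CPM in control and 138.8 ± 10.8 CPM in cHet (log2 fold change 0.34, SE 0.0985). With edgeR p-values adjusted over the list alone, Rcor2 was higher (adjusted p = 0.0311) and 4 erythroid genes (among them the globins Hbb-bt, Hbb-bs and Hba-a1) and C1qc were lower. In all, 13 of the 33 lists passed.

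In the LoF polysome, choroid plexus and hem markers were lower for 12 of 12 members (median -1.05, adjusted p = 1.25e-05, and adjusted p = 0.779 with an estimated correlation), among them Ttr (20.3 ± 17.2 CPM in control, 1.86 ± 3.10 CPM in cHet). Cajal-Retzius cell markers were lower for 8 of 8 (median -0.19, adjusted p = 0.0211, and adjusted p = 0.779 with an estimated correlation) and interneuron markers for 13 of 14 (median -0.28, adjusted p = 0.00899, and adjusted p = 0.779 with an estimated correlation). Cell cycle genes were higher for 20 of 25 (median 0.09, adjusted p = 0.0249, and adjusted p = 0.805 with an estimated correlation), a call lost with the GC and length correction (adjusted p = 0.0614). These were 4 of 5 lists called, and the last was that of ventral forebrain progenitors (7 of 10 lower, median -0.29, adjusted p = 0.0249, and adjusted p = 0.779 with an estimated correlation). No member passed adjusted over the list alone. For single genes edgeR called 0 of 18556, with 600 at an unadjusted p under 0.05, and DESeq2 called 0. The smallest p-values were those of Saxo2 (0.752 ± 0.276 to 0.274 ± 0.0298 CPM), Gm36787 (0 to 0.0988 ± 0.0212 CPM) and Gm5380 (0.0307 to 0.393 ± 0.275 CPM), each with an adjusted p of 1. Without control 2 the count was 12, and without cHet 1 it was 1.

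Whether ribosome loading changed in LoF cHet was tested as the change of polysome over input and over monosome. Gm15564 (log2 fold change -2.70, adjusted p = 0.0135) and the microRNA gene Mir6236 (log2 fold change -2.94, adjusted p = 0.0417) fell in polysome over input. Mir6236 was at 4.58 ± 1.74 CPM in control and 17 ± 1.22 CPM in cHet input, against 24.3 ± 2.36 and 11.8 ± 5.45 CPM in the polysome. With the lysate as a replicate block both were lost (adjusted p = 0.0862 for Gm15564 and 0.202 for Mir6236), which left a count of 0. CT010467.1, over the ribosomal RNA precursor and chosen after its values were seen, was higher in cHet input and lower in cHet polysome too, but did not pass (polysome over input log2 fold change -2.72, adjusted p = 0.558). It took 2.31 ± 0.321% of the polysome read pairs in control and 1.36 ± 1.04% in cHet. In cHet polysome pools 1, 2 and 3 it took 2.57, 0.753 and 0.77%, with Mir6236 at 18, 9.16 and 8.08 CPM, so a change of loading cannot be told apart from the amount of ribosomal RNA in the libraries. CT010467.2, the next in order, had a log2 fold change of -3.28 (adjusted p = 0.0671). Ribosomal protein mRNAs were lower in polysome over input for 70 of 76 members (median -0.14, adjusted p = 2.74e-07, and adjusted p = 0.972 with an estimated correlation), opposite to their higher level in input. As the input effect is subtracted in this comparison, their higher input level alone would give that sign. A change of their loading is thus not shown. In polysome over monosome, mitochondrially encoded mRNAs were higher for 10 of 10 (median 0.74, adjusted p = 0.000195, and adjusted p = 0.632 with an estimated correlation), erythroid genes for 11 of 12 (median 0.43, adjusted p = 0.00964, and adjusted p = 0.67 with an estimated correlation), microglial markers for 10 of 12 (median 0.44, adjusted p = 0.00283, and adjusted p = 0.177 with an estimated correlation) and cell cycle genes for 23 of 25 (median 0.13, adjusted p = 0.0052, and adjusted p = 0.67 with an estimated correlation). Mitochondrial read pairs were 7.89 ± 2.03% in control and 5.78 ± 1.01% in cHet monosome libraries. In the polysome they were 0.02738 ± 0.009385% and 0.03078 ± 0.0091%. Mitochondrially encoded mRNAs are translated by other ribosomes, so their rise does not show a change of loading. Of the 13 lists called in polysome over monosome, nuclear oxidative phosphorylation and small RNA host genes were lost with the lysate block (adjusted p = 0.0683 and 0.0594). EdgeR called 2 of 18556 genes in polysome over input (1275 at an unadjusted p under 0.05, DESeq2 5) and 0 in polysome over monosome (561, DESeq2 0), where the smallest p-values were those of Gm5560, Efcab15 and Sat1 (adjusted p = 1). Without cHet 1 the count in polysome over input was 18, without control 3 it was 1, and without any other library it was 0.

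Input of T532M cHet against control was tested in the same way, here with Cre in both genotypes. Ribosomal protein mRNAs were lower for 76 of 77 members (median -0.23, adjusted p = 6.07e-21, and adjusted p = 0.798 with an estimated correlation), such as Rps29 (150.4 ± 17.5 to 102.5 ± 8.75 CPM). Nuclear oxidative phosphorylation genes were lower for 35 of 35 (median -0.24, adjusted p = 4.31e-12, and adjusted p = 0.798 with an estimated correlation). Choroid plexus and hem markers were higher for 12 of 12 (median 2.68, adjusted p = 0.00949, and adjusted p = 0.817 with an estimated correlation) and meningeal ones for 11 of 11 (median 0.69, adjusted p = 0.0242, and adjusted p = 0.817 with an estimated correlation). Ttr was at 177, 2.25 and 0 CPM in cHet pools 1, 2 and 3 and at 0.200, 0 and 0.0608 CPM in control pools, so cHet 1 carried most of it. Reported DDX3X-sensitive mRNAs were higher for 9 of 12 (median 0.12, adjusted p = 0.0213, and adjusted p = 0.798 with an estimated correlation). Among them the ornithine decarboxylase gene Odc1 was at 352.6 ± 3.93 CPM in control and 471.8 ± 18.3 CPM in cHet. With p-values adjusted over the list alone, Odc1 and Topbp1 were higher and Rps29 lower. Of 18243 genes 1 rose by edgeR, with 1956 at an unadjusted p under 0.05 and 123 by DESeq2. It was Gm49760 (0.0753 ± 0.0129 to 0.420 ± 0.126 CPM, log2 fold change 2.44, adjusted p = 0.00799), which was lost without control 1 or 3 (adjusted p = 0.246 and 0.299), without cHet 1 or 3 (0.167 and 0.0997) and in a fit on input alone (0.677). Next came the NAD kinase gene Nadk2 (18.2 ± 3.49 to 28.7 ± 2.76 CPM) and the retinoid receptor gene Rxra (35.3 ± 3.47 to 54.0 ± 5.32 CPM), both with an adjusted p of 0.127. Without control 2 the count was 543, without cHet 2 it was 1, and without any other library it was 0.

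In the T532M monosome most changes were rises. Topbp1, a scaffold of the replication checkpoint, rose from 109.9 ± 14.6 to 285.1 ± 35.2 CPM (log2 fold change 1.38, SE 0.256, adjusted p = 0.0127). Rcor2, a corepressor of the LSD1 complex (chromosome 19, 7267325 to 7275225, plus strand), rose from 125.8 ± 11.4 to 269.9 ± 47.8 CPM (log2 fold change 1.10, SE 0.154, adjusted p = 0.00206). Dvl3, a Wnt signal transducer, rose from 114.4 ± 7.58 to 232.8 ± 31.3 CPM and the histone demethylase gene Phf2 from 168.4 ± 20.5 to 337.6 ± 54.7 CPM. Cadps2, a priming factor of vesicle release, rose from 5.74 ± 0.35 to 12.8 ± 1.27 CPM and Ankrd13a from 73.65 ± 2.74 to 143.2 ± 12.6 CPM. The other named rises were Eya2 (log2 fold change 1.17), Slc49a4 (0.95), Pcolce2 (0.94) and Pdk1, whose levels are given below. The named falls were Dpf3, a subunit of the BAF chromatin remodeler (8.39 ± 2.13 to 4.36 ± 0.344 CPM), Ndnf (5.32 ± 1.24 to 3.02 ± 0.161 CPM), the adhesion gene Cadm2 (38.96 ± 6.08 to 23.55 ± 2.73 CPM), Acot1 (log2 fold change -0.64), Serinc5 (-0.61), Acp2 (-0.52), Zfp773 (-0.48), Tmem135 (-0.40) and Ikbkg (-0.40). EdgeR called 188 of 18243 genes (178 higher, 10 lower), with 2144 at an unadjusted p under 0.05, and DESeq2 called 582 (67.4% higher, 190 genes lower). Without control 1, 2 or 3 the count was 26, 636 and 7, and without cHet 1, 2 or 3 it was 57, 39 and 104. It was 307 in a fit on the monosome alone and 448 with the correction for GC content and length. Rises were 58% of the calls without control 2 and 73.4% without the low-count filter. Cadps2, Ankrd13a, Phf2 and Dvl3 passed under every alternative run. The 178 genes that rose had a median log2 fold change of 0.56 in the monosome, 0.24 in input and 0.05 in the polysome. They were picked by their rise in these monosome libraries, so a larger median there is partly set by the choice. In monosome over input, added after seeing the data, the median of the 178 genes was 0.35 and 0 passed. In the LoF monosome 166 of them lay above 0 (median 0.15) and 0 passed. In LoF input 132 lay above 0 (median 0.08) and 0 passed. Over all genes the LoF monosome effect had a median of 0.0112 and a median size of 0.125. Genes that move together are not independent, and these counts were not set against splits of the pools.

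Among the fixed lists in the T532M monosome, reported DDX3X-sensitive mRNAs were higher for 10 of 12 members (median 0.31, adjusted p = 3.35e-06, and adjusted p = 0.207 with an estimated correlation). Of these Rcor2, Odc1 (303.4 ± 20.6 to 441.7 ± 17.4 CPM, log2 fold change 0.54) and Topbp1 passed over all genes, and 6 passed adjusted over the list alone, with Klf4, Fam136a and Ccne1 added. Hypoxia and glycolysis genes were higher for 14 of 15 (median 0.22, adjusted p = 7.69e-05, and adjusted p = 0.327 with an estimated correlation), with Pdk1, which holds back pyruvate oxidation (33.6 ± 3.16 to 65.75 ± 7.32 CPM), and the mitophagy gene Bnip3 (11.23 ± 0.235 to 17.02 ± 2.95 CPM) past the threshold. Wnt targets were higher for 9 of 11 (median 0.26, adjusted p = 0.0254, and adjusted p = 0.637 with an estimated correlation), with Nkd1, a Wnt antagonist, rising from 54.48 ± 0.709 to 75.23 ± 6.03 CPM. Jund of the immediate early list rose from 178.4 ± 6.75 to 278.1 ± 31.8 CPM, while that list did not pass. Axon guidance genes were lower for 20 of 22 (median -0.34, adjusted p = 0.0015, and adjusted p = 0.637 with an estimated correlation), DEAD/DEAH-box helicases for 27 of 28 (median -0.17, adjusted p = 0.00819, and adjusted p = 0.893 with an estimated correlation) and excitatory neuron markers for 12 of 17 (median -0.27, adjusted p = 0.0243, and adjusted p = 0.893 with an estimated correlation). The neuronal microtubule gene Dcx was at 733.8 ± 157 CPM in control and 483.1 ± 26.2 CPM in cHet. Choroid plexus and hem markers were higher for 12 of 12 (median 2.61, adjusted p = 0.0254, and adjusted p = 0.921 with an estimated correlation), meningeal markers for 11 of 11 (median 0.41, adjusted p = 0.0195, and adjusted p = 0.921 with an estimated correlation) and replication-dependent histones for 7 of 10 (median 0.32, adjusted p = 0.0254, and adjusted p = 0.327 with an estimated correlation). With the GC and length correction 5 of the 11 lists called stayed, and Wnt targets (adjusted p = 0.0755), choroid plexus (0.0932), meninges (0.0755) and histones (0.0932) were among those lost.

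**Figure D3:**
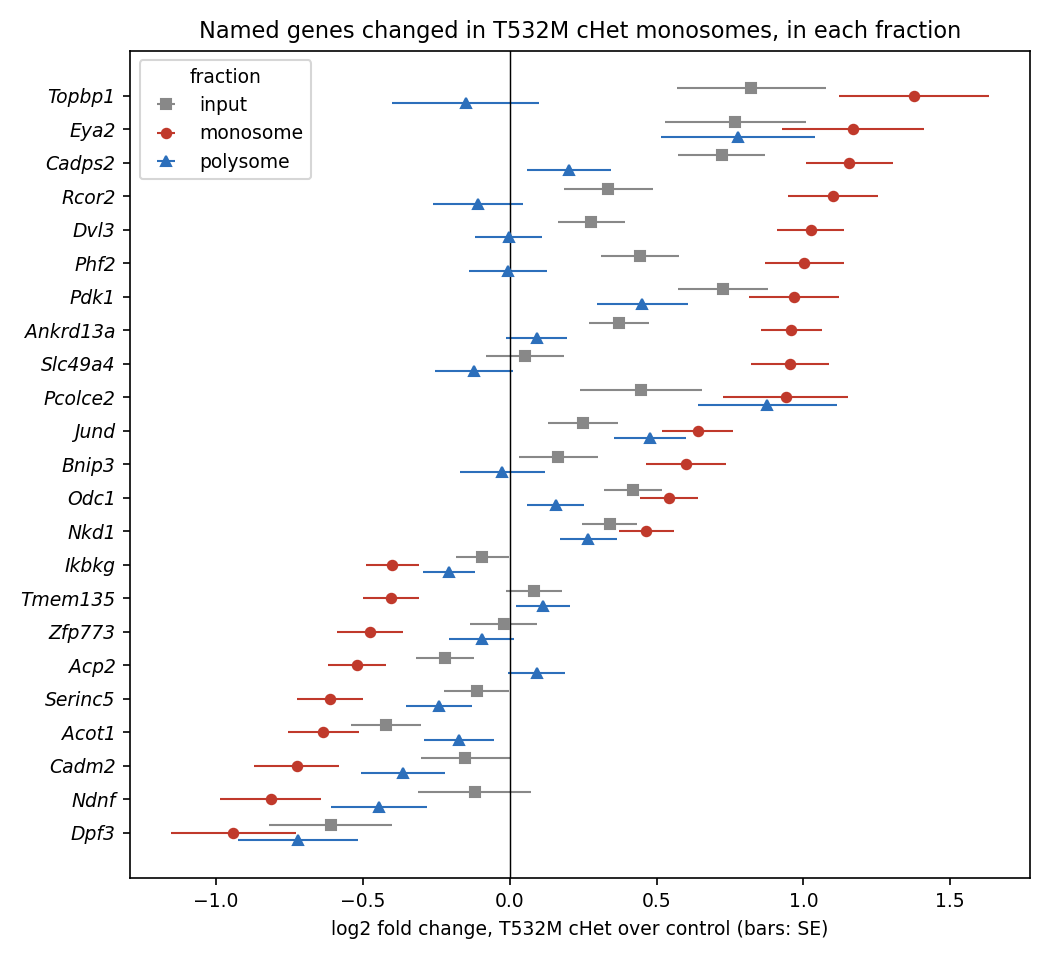
Log2 fold change of T532M cHet over control (horizontal axis, with SE) for named genes that changed in the monosome (vertical axis), in input (grey squares), monosome (red circles) and polysome (blue triangles). Topbp1 has a log2 fold change of 1.38 in the monosome, and Dpf3 one of -0.94.

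In the T532M polysome excitatory neuron markers were lower for 17 of 17 members (median -0.35, adjusted p = 1.11e-05, and adjusted p = 0.429 with an estimated correlation). The neuronal transcription factor Neurod6 was at 348.9 ± 40.4 CPM in control and 236.7 ± 81.2 CPM in cHet, and Bcl11b, which marks deep-layer neurons, at 1201 ± 186 and 899.6 ± 98.2 CPM. Hypoxia and glycolysis genes were higher for 14 of 15 (median 0.24, adjusted p = 1.11e-05, and adjusted p = 0.332 with an estimated correlation), with the lactate dehydrogenase gene Ldha at 576.7 ± 69.9 and 785 ± 114 CPM. Cell cycle genes were higher for 23 of 25 (median 0.20, adjusted p = 0.000621, and adjusted p = 0.79 with an estimated correlation), apical progenitor markers for 12 of 14 (median 0.24, adjusted p = 0.00374, and adjusted p = 0.701 with an estimated correlation) and interferon response genes for 13 of 14 (median 0.66, adjusted p = 0.000621, and adjusted p = 0.332 with an estimated correlation). Choroid plexus and hem markers were higher for 11 of 12 (median 2.97, adjusted p = 0.000132, and adjusted p = 0.701 with an estimated correlation), and 5 of them passed adjusted over the list alone. Meningeal markers were higher for 9 of 11 (median 0.81, adjusted p = 0.00204, and adjusted p = 0.79 with an estimated correlation). In all, 13 of the 33 lists passed. EdgeR called 0 of 18243 genes, 1444 had an unadjusted p under 0.05, and DESeq2 called 3. The smallest p-values were those of the mitochondrial carrier gene Ucp2 (4.55 ± 0.173 to 8.50 ± 1.61 CPM, adjusted p = 0.0947), C920006O11Rik (log2 fold change -1.37, adjusted p = 0.158) and the adenylate kinase gene Ak4 (17.5 ± 2.76 to 28.2 ± 2.35 CPM, adjusted p = 0.158). Without control 2 the count was 139, and without cHet 2 it was 1.

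Ribosome loading in T532M cHet was tested as polysome over monosome and over input. Rcor2 fell in polysome over monosome (log2 fold change -1.21, adjusted p = 0.0486). Its monosome level rose as given above, while its polysome level was 252.8 ± 10.8 CPM in control and 234.6 ± 37.4 CPM in cHet. Gnb1, a G protein subunit, fell too (log2 fold change -0.90), with 904.6 ± 19.4 and 1474 ± 62.0 CPM in the monosome against 609.9 ± 47.4 and 531.1 ± 57.7 CPM in the polysome. Mta1, of the NuRD complex (log2 fold change -0.92), was at 195 ± 18.8 and 372 ± 44.9 CPM in the monosome and 140.3 ± 4.84 and 141.2 ± 9.15 CPM in the polysome. Prkaca, the catalytic subunit of protein kinase A (log2 fold change -0.72), was at 101.7 ± 3.22 and 146.4 ± 4.38 CPM in the monosome and 74.2 ± 0.854 and 64.7 ± 4.43 CPM in the polysome. The others were Slc49a4 (-1.08), Dvl3 (-1.03), Zbtb12 (-0.88), Ankrd13a (-0.87), Nck2 (-0.84) and Klhdc2 (-0.73), and Gm12999, which is outside the naming rule and was chosen after its values were seen. EdgeR thus called 11 of 18243 genes, all lower with an adjusted p of 0.0486, with 1249 at an unadjusted p under 0.05, and DESeq2 called 83. The count was 22 with the lysate as a replicate block, 44 with the GC and length correction, 166 with both, 0 with RLE factors and 0 without any 1 of the 6 pools (controls 1, 2 and 3, cHet 1, 2 and 3).

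Reported DDX3X-sensitive mRNAs were lower in T532M polysome over monosome for 9 of 12 members (median -0.30, adjusted p = 0.00193, and adjusted p = 0.999 with an estimated correlation), of which Rcor2 passed over all genes and Rcor2 and Topbp1 adjusted over the list alone. DEAD/DEAH-box helicases were higher for 27 of 28 (median 0.23, adjusted p = 0.000132, and adjusted p = 0.999 with an estimated correlation). Other TOP-motif genes were higher for 17 of 20 (adjusted p = 0.0354, and adjusted p = 0.999 with an estimated correlation), a call lost with the lysate block (adjusted p = 0.0693). In polysome over input, ribosomal protein mRNAs were higher for 77 of 77 (median 0.22, adjusted p = 2.44e-16, and adjusted p = 0.811 with an estimated correlation), the reverse of their lower level in input. Nuclear oxidative phosphorylation genes were higher for 31 of 35 (median 0.14, adjusted p = 2.22e-05, and adjusted p = 0.811 with an estimated correlation). As the input effect is subtracted in this comparison, the lower input levels of both lists would alone give such rises. A change of their loading is thus not shown. Mitochondrial ribosomal protein genes were higher for 21 of 25 (adjusted p = 0.0389, and adjusted p = 0.811 with an estimated correlation), a call lost with the lysate block (adjusted p = 0.0542) and with the GC and length correction (adjusted p = 0.428). For single genes in polysome over input edgeR called 0 of 18243, with 1113 at an unadjusted p under 0.05, and DESeq2 called 0. Gm49760 (adjusted p = 0.19), Gm28424 and Zfp677 (0.793 each) had the smallest p-values.

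The crosses were compared as the LoF effect minus the T532M effect, each against its own control, and these controls differ in Cre. Ifih1, a sensor of double-stranded RNA, differed in input (log2 difference -3.53, SE 0.473, adjusted p = 0.000447). It was at 0.429 ± 0.0279 CPM in LoF control and 0.145 ± 0.0656 CPM in LoF cHet, against 0.0821 ± 0.00288 and 0.322 ± 0.103 CPM in the T532M cross. Nadk2 differed too (log2 difference -1.17, SE 0.212, adjusted p = 0.0499), with 21.9 ± 4.54 and 15.5 ± 2.05 CPM in the LoF cross, and Hfm1 did not pass (adjusted p = 0.0558). In polysome over input Ifih1 differed the other way (log2 difference 3.45, SE 0.553, adjusted p = 0.0129), a call lost with the lysate as a replicate block (adjusted p = 0.0832). In the polysome Saxo2 (adjusted p = 0.0744), the sialidase gene Neu1 (0.139) and Ucp2 (0.209) had the smallest p-values. EdgeR called 2 of 19121 genes in input (3047 at an unadjusted p under 0.05, DESeq2 750), 0 in the polysome (1068, DESeq2 4) and 1 in polysome over input (2082, DESeq2 12). The count in input was 330 without LoF control 2, 39 without LoF control 3, 802 without LoF cHet 2, 1697 without T532M control 2 and 670 without T532M cHet 3. It was 1 without LoF control 1, LoF cHet 1, T532M control 1, T532M cHet 1 or T532M cHet 2. In the polysome it was 2 without LoF control 2 and 1 without T532M control 2 or T532M cHet 2. In polysome over input it was 0 without LoF control 1 or 2, LoF cHet 1 or 2, T532M control 1 or 2 or T532M cHet 1 or 3, and 2 without LoF cHet 3 or T532M control 3.

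Across 18030 genes tested in both crosses, Spearman's correlation of the LoF and T532M effects was -0.322 in input, 0.0409 in the polysome and -0.229 in polysome over input. Genes are not independent replicates, and of the 100 combinations of splits of the pools 16, 73 and 26 gave a correlation as far from 0. The polysome value changed sign as a Pearson correlation (-0.0876).

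The authors' deposited tables hold their own tests. At an adjusted p under 0.05, the authors' deposited table of the LoF cross lists 70 genes in input (11 higher, 59 lower), 0 in monosome over input and 1 in polysome over input (Filip1l, log2 fold change -2.24, adjusted p = 0.00854). The authors' deposited table of the T532M cross lists 123 genes in input (87 higher, 36 lower), 51 in monosome over input (48 higher, 3 lower) and 1 in polysome over input. Among the 51 is Prkaca, with a log2 fold change of 0.64 and an adjusted p of 2.59e-13 in the authors' deposited table. All 70 and all 123 input genes had the same sign and an unadjusted p under 0.05 in the fits described here. Both rest on the same counts, so this is no separate test. After adjustment edgeR called 0 of 18556 genes in LoF input and 1 of 18243 in T532M input.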

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

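The tests of these differences were fixed beforehand, and only the correction for GC content and length was chosen after the results were seen. Ifih1, which encodes a sensor of double-stranded RNA, drew attention because the LoF and T532M effects on its input level differed in a test of the difference itself (log2 difference -3.53, SE 0.473, adjusted p = 0.000447, edgeR). Its level lay between 0.0821 ± 0.00288 and 0.429 ± 0.0279 CPM in the input groups (SD, n = 3), which is low. Nadk2, a mitochondrial NAD kinase gene, was picked out by the same test of input (log2 difference -1.17, SE 0.212, adjusted p = 0.0499). Ifih1 also differed in polysome over input, with the opposite sign (log2 difference 3.45, SE 0.553, adjusted p = 0.0129), while its polysome level was 6.42 ± 0.502 and 7.28 ± 1.25 CPM in LoF control and cHet and 6.30 ± 1.19 and 7.60 ± 0.740 CPM in T532M control and cHet. The input difference of Ifih1 passed under every alternative that gave an adjusted p. DESeq2 gave none, since its filter left this gene out of the adjustment (log2 difference -3.53, SE 0.641, unadjusted p = 3.57e-08). That of Nadk2 was lost without LoF control 1 (adjusted p = 0.329), LoF cHet 1 (0.173) or 3 (0.0856), T532M control 1 (0.209) or 3 (0.0968) and T532M cHet 1 (0.257) or 2 (0.0808), and with the GC and length correction (0.069). The polysome over input difference of Ifih1 was lost with the lysate as a block (adjusted p = 0.0832), with the GC and length correction (0.347), with both (0.405), and without LoF control 1 (0.0962) or 2 (0.103), LoF cHet 1 (0.0901) or 2 (0.0528), T532M control 1 (0.056) or 2 (0.128) or T532M cHet 1 (0.144) or 3 (0.0912).

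Splits of the pools within the crosses, 30 for each difference with the real one among them, were counted. In input 3 of 30 gave as many genes as the real 2, with 673 in the highest, so chance was not excluded, and splits with several times the real count point to a structure of the input libraries that does not follow genotype. In polysome over input 1 of 30, the real one itself, gave as many as the real 1, and the highest other gave 0. That share is under 0.05, but these fits leave out the shared lysate and the count is a single gene, which is lost with the lysate block and without 8 of the 12 pools, so chance is left open. In the polysome 30 of 30 gave at least the real 0 (highest other 67). The 2 differences added after seeing the data gave 30 of 30 in the monosome (real 0, highest other 172) and 30 of 30 in polysome over monosome (real 0, highest other 0).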

How the results depend on the processing

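Chosen after seeing the data were the GC and length correction, the fits without the 3 LoF pools with most Ttr and the comparisons of monosome over input and of the crosses in the monosome and in polysome over monosome. Leaving out the low-count filter changed most counts of genes: 967, 33, 41, 193 and 2 in LoF input, monosome, polysome, polysome over input and polysome over monosome, 157, 58 and 7 in T532M input, polysome and polysome over monosome, 1163, 51, 256 and 36 between crosses in input, polysome, polysome over input and monosome, and 88 and 4 in LoF and T532M monosome over input. DESeq2 gave 81, 5 and 5 in LoF input, monosome and polysome over input, 123, 582, 3 and 83 in T532M input, monosome, polysome and polysome over monosome, 750, 4, 12 and 47 between crosses in input, polysome, polysome over input and monosome, and 42 in T532M monosome over input. The GC and length correction gave 0 in LoF polysome over input, 12, 448, 2 and 44 in T532M input, monosome, polysome and polysome over monosome, 1, 0 and 59 between crosses in input, polysome over input and monosome, and 0 in T532M monosome over input. Without the 3 Ttr pools, where the lone LoF control is assumed to vary like the other groups, counts were 62, 940, 70, 16, 203 and 123 in LoF input, monosome, polysome, polysome over input, polysome over monosome and monosome over input. The fit of all 36 libraries gave 4 in LoF input, 24, 2 and 33 in T532M input, polysome and polysome over monosome and 0 in T532M monosome over input. Fits on 1 fraction gave 1 in LoF monosome and 0 and 307 in T532M input and monosome. RLE factors gave 1 and 0 in T532M polysome and polysome over monosome. With the pool number as a replicate block, a pairing of control and cHet that the labels do not give and the data did not show over all pairs (6 of 18 pairs correlated best with their own number, among them all those of T532M monosome, r = 0.0804, 0.134 and 0.154), counts were 1 in LoF polysome over input, 21, 349, 4, 17 and 3 in T532M input, monosome, polysome, polysome over monosome and monosome over input and 34, 1 and 14 between crosses in input, polysome and monosome. With the lysate as a replicate block they were 0 in LoF polysome over input, 22 and 3 in T532M polysome over monosome and monosome over input and 0 between crosses in polysome over input, and it changed no other count by over 1.5 times. With lysate block and GC correction they were 0, 166, 4, 0 and, between crosses in polysome over monosome, 3. Of 330 list tests 85 were called, 0 with an estimated correlation, 1 by fry and 66 with the GC and length correction (59 of them among the 85). With that correction 9 of 13 stayed in LoF polysome over monosome and 3 of 6 in T532M polysome over input. Without each pool in turn, counts ran from 0 to 15, 1 to 180, 0 to 12, 0 to 18 and 0 to 0 in LoF input, monosome, polysome, polysome over input and polysome over monosome, from 0 to 543, 7 to 636, 0 to 139, 0 to 0 and 0 to 0 in T532M, from 1 to 1697, 0 to 2, 0 to 2 and 0 to 43 between crosses in input, polysome, polysome over input and monosome, and from 0 to 1 in T532M monosome over input. In control polysome against monosome they ran from 13935 to 14427 (LoF, 13758 to 14137 of them also called with all pools) and from 13619 to 13800 (T532M, 13428 to 13554). The polysome correlation between crosses was -0.0876 as Pearson's. Ddx3x changes that turned sign were none of the called ones: LoF polysome over input was -0.00699 with DESeq2, -0.37 with GC correction, -0.48 without the Ttr pools, -0.00624 with RLE, -0.0225 and -0.0132 with pool number and lysate block, -0.39 with lysate block and GC correction and -0.24 without control 1, and it ran from -0.36 to 0.32 without each pool in turn. LoF input was 0.0353 with GC correction and 0.22 without the Ttr pools. T532M monosome was 0.055 with GC correction, 0.0219 without cHet 1, and it ran from -0.15 to 0.0453 without each pool. T532M polysome over input was 0.0938 with GC correction, 0.0622 with lysate block and GC correction, 0.083 without cHet 1, and it ran from -0.40 to 0.17 without each pool. Of 77 values of named genes, 42 past the threshold, 1083 alternatives with an adjusted p kept 766 on their side, weakened 226, strengthened 73 and reversed 18, and 6 never weakened (Cadps2, Ankrd13a, Phf2, Dvl3, Gm5380 and Ifih1 in input). For 3 more values there was no adjusted p: Ifih1 in input with DESeq2, and Gm36787 and Gm5380 in LoF polysome in the fit on 1 fraction, where the low-count filter removed them. Except where fewer pools show it, the cause was not tested.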

Other observations

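Tests chosen only after the results were seen were the comparisons with the monosome over input and between crosses in the monosome and in polysome over monosome, the fits without the 3 LoF pools with most Ttr, the correction for GC content and length, the 2 tests of 5' UTR GC content, the test of a GC bias of input libraries and that of transcription past Ddx3x. In LoF cHet input, intermediate progenitor markers were higher for 10 of 12 members (median log2 fold change 0.12, adjusted p = 0.0201, and adjusted p = 0.648 with an estimated correlation) and hypoxia genes for 13 of 15 (adjusted p = 0.0459, and adjusted p = 0.648 with an estimated correlation), both lost with the GC and length correction (adjusted p = 0.577 and 0.31). In the LoF cHet monosome, Wnt targets were lower for 11 of 12 (median -0.21, adjusted p = 0.0134, and adjusted p = 0.306 with an estimated correlation), while in the T532M cHet polysome 9 of 11 were higher (median 0.27, adjusted p = 0.0116, and adjusted p = 0.519 with an estimated correlation). Genes of the integrated stress response, targets of Atf4, were higher in the T532M cHet polysome for 13 of 18 (median 0.20, adjusted p = 0.00652, and adjusted p = 0.332 with an estimated correlation). Unfolded protein response genes were higher in LoF polysome over monosome for 13 of 14 (median 0.16, adjusted p = 0.0118, and adjusted p = 0.26 with an estimated correlation). The lists of p53 targets (lowest adjusted p = 0.267), translation initiation factors (0.196), nuclear long non-coding RNAs (0.271) and cholesterol biosynthesis (0.113) passed in none of the 10 comparisons.

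In monosome over input, edgeR called 0 of 18556 genes in the LoF cross (936 at an unadjusted p under 0.05, DESeq2 0) and 1 of 18243 in the T532M cross (1079, DESeq2 42). It was Gm49760 (log2 fold change -2.73, adjusted p = 0.0166), named after its values were seen and lost without any pool but cHet 2. The T532M count was 3 with the lysate as a replicate block and 0 with the GC and length correction. Between the crosses it called 0 of 19121 in the monosome (1279, DESeq2 47) and 0 in polysome over monosome (593, DESeq2 0). Without T532M control 2 the count between crosses in the monosome was 43, and without T532M cHet 2 it was 1. Genes that rose in the T532M cHet monosome had GC-rich 5' UTRs, with a median GC content of 76.9% in the 173 with known features, against 65.4% over 10410 protein-coding genes. Among 10000 sets of genes matched on coding GC, coding length and abundance the highest median was 70.8%. These sets draw genes as if independent, so they show a shared feature and not that it follows genotype. Genes called in other splits of the pools were not compared in this way. Among named genes the 5' UTR GC content ran from 51.2% (Eya2) to 88.4% (Phf2) in those that rose and from 37.5% (Dpf3, over 8 bases) to 73.9% (Tmem135) in those that fell, so the ranges overlap.

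The first pattern is that 178 of the 188 genes changed in the T532M cHet monosome rose: with libraries corrected for transcript GC content and length, the median rise of these 178 genes was 1.02 times its value before and 175 were still called, which argues against transcript GC or length as the whole cause. The correction used the GC content of whole transcripts, so it does not address a library bias tied to GC of the 5' UTR. Without cHet pool 1, which carried most Ttr, the median rise was 1 times its value, with 56 of 178 still called in the smaller design, which argues against RNA of the choroid plexus in that pool. With RLE factors in edgeR 90.8% of calls were rises, so the pattern did not hang on the choice between TMM and RLE. Both take most genes as unchanged, so scaling is left open. The share of rises was 67.4% with DESeq2, 73.4% without the low-count filter and 58% without control 2. A candidate explanation, found on these same data, is that mRNAs with GC-rich 5' UTRs move to the monosome, or lose polysomes relative to it, when DDX3X is impaired: the partial correlation of the effect with 5' UTR GC, summed over the crosses, was 0.43 in the monosome, as extreme in 2 of 400 signed split combinations (the real one among them), and -0.39 in polysome over monosome, as extreme in 4 of 400. The sums rest mainly on T532M (0.296 and -0.28), the cross in which the rises were seen. They are thus no separate test of the idea. In LoF alone 2 of 20 signed splits were as extreme in the monosome and 3 of 20 in polysome over monosome. Another LoF split reached 0.169 against 0.135 in the monosome and 0.173 in size against -0.108 in polysome over monosome. Another T532M split reached 0.237 in size against 0.296 in the monosome, and 0.218 in size against -0.28 in polysome over monosome. In input that split reached 0.224 in size against 0.257. A split that mixes the genotypes thus came near the real values in T532M too. The input effect showed the trend as rarely (0.257 in T532M and 0.0663 in LoF, 3 of 400). That goes against a shift of loading alone. In monosome over input the partial correlation was 0.0966 in T532M and 0.0568 in LoF, where another split reached -0.102. The polysome effect showed no such trend (0.0263, 167 of 400). Polysome over input (sum -0.298, 17 of 400, in LoF alone 9 of 20) therefore restates the trend in input. It cannot tell a loss of loading from a bias of the input libraries.

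The second pattern is that input effects followed transcript GC content across genes (Spearman's correlation 0.732 in LoF and -0.461 in T532M). In LoF the larger correlation in the monosome or polysome was 0.301 times that in input, as a GC bias of the input libraries needs, since fractions of the same lysates carried it weakly (0.221 and -0.145). In T532M the monosome and polysome had 0.157 and 0.125, the opposite sign to input. A GC bias may therefore contribute to the LoF input lists, of which 3 of 11 stayed with the GC and length correction, while 8 of 9 did in T532M input, and ribosomal proteins stayed in both (adjusted p = 0.000825 and 9.67e-06). In LoF, 1 of the 10 splits was as far from 0 (real 0.732, highest other 0.72), too few for a share under 0.05, and in T532M 5 of 10 were (highest other 0.68), so other splits of the pools held the trend. No biological explanation was tested.

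The third pattern is the rise of Gm5380 and Nyx, which lie downstream of Ddx3x on its strand, in LoF cHet. Cre, which LoF controls lack, was excluded as the cause of Gm5380, since T532M controls carry Cre and had 0 read pairs of it in the monosome. A candidate explanation is transcription running past the recombined Ddx3x gene: upstream neighbours, on its strand (Usp9x, Rpl3-ps1) or on the other (Llph-ps2, 2010308F09Rik), had a median log2 fold change of -0.038 (-0.04). No downstream neighbour on the other strand within 200 kb was among the genes tested. That explanation cannot be told apart from others here. For Nyx the LoF effect did not exceed that in T532M past the threshold, adjusted over 19121 genes (log2 difference 2.52, SE 0.648, adjusted p = 0.308, edgeR). Gm5380 had 0 read pairs in the T532M cHet monosome against 380 in LoF cHet, so T532M cHet lacked its rise. With 0 in the T532M control too, edgeR could not test that difference (SE 10900). Read pairs of Nyx were 45 and 244 in LoF control and cHet monosome and 64 and 60 in T532M, but 15 and 32 in T532M input (ratio 2.1, 95% counting interval 1.11 to 4.18, adjusted p = 0.57 by edgeR) and 27 and 70 in LoF input (ratio 2.75, 1.74 to 4.45).

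Splits of the 6 pools of a cross into 3 and 3 number 10 with the real one among them, too few for a share under 0.05, and are given as counts. Their fits leave out the shared lysate, also in the comparisons across fractions. For genes changed in LoF, as many as the real value came from 10 splits in input (real 0, highest other 282), 3 in the monosome (2, 295), 10 in the polysome (0, 10), 1 in polysome over input (2, 0), 10 in polysome over monosome (0, 4) and 10 in monosome over input (0, 0). In T532M they came from 5 in input (1, 258), 1 in the monosome (188, 8), 10 in the polysome (0, 213), 10 in polysome over input (0, 0), 1 in polysome over monosome (11, 0) and 1 in monosome over input (1, 0). For controls of LoF and T532M, polysome against monosome, 1 of 10 did (15076 and 14582, highest other 0 in both). The splits that called 282, 295, 258 and 213 genes point to a structure of the pools apart from genotype. The split that puts the 3 LoF pools with most Ttr together called 2, 0 and 10 genes in input, monosome and polysome, and the source of 282 and 295 was not tested. The 258 and 213 both came from the split that sets T532M control 2, cHet 1 and cHet 2 apart. For lists called, as many came from 3 splits in LoF input (11, 13), 2 in its monosome (13, 13), 9 in its polysome (5, 9), 10 in polysome over input (1, 11) and 1 in polysome over monosome (13, 9). In T532M they came from 5 in input (9, 14), 5 in the monosome (11, 13), 6 in the polysome (13, 15), 3 in polysome over input (6, 8) and 6 in polysome over monosome (3, 7). Of the 100 combinations for the correlation between crosses, 16 were as far from 0 in input (real -0.322, highest other 0.427), 73 in the polysome (0.0409, 0.335) and 26 in polysome over input (-0.229, 0.324), so chance was not excluded.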
